A study of Mus musculus with 4 samples.

How the data were processed

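RNA from mouse heart at postnatal day 14 was sequenced in 4 libraries, 2 wild type and 2 labelled Carm1 mutant. Per the labels, libraries were prepared by BGI from total RNA; the allele, the sex of the animals and whether the kit kept strand are not given in the sources used here. The series text calls the hearts neonatal while the sample labels give day 14. Per the submitters' processing notes, FastQC and HISAT2 were used with the mm10 build. Versions, the counting program, its gene annotation and its treatment of reads that match several places are not given in the sources used here. The deposited values are raw counts per gene, whole numbers that differ in total between libraries, and were used as the authors deposited them.

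Columns were matched to samples by their titles, and samples were grouped by genotype label. Of 54752 identifiers 54723 had a name in GENCODE M21, which is built on the same assembly as mm10, and 29 had none; coordinates are from that release, counted from 1. Rows without a name held at most 0.00106% of a library and name gene identifiers, so they were kept. In 28283 rows every library had 0. Replicates were compared by a chi-square test over genes with at least 10 counts per pair. Chi-square per degree of freedom was 51.1 between the wild-type libraries and 11.5 between the mutant-labelled ones. No library thus repeated another within counting error. This does not show whether libraries came from separate animals or separate RNA.

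Genes were kept with filterByExpr at its default settings, which left 15283. Libraries were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test (glmQLFit, glmQLFTest) with genotype as the only term and 2 residual degrees of freedom, and adjusted by Benjamini-Hochberg (FDR in the text) with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-normalised unless library totals are named, and ± is the SD of 2 libraries. TMM factors were 0.806 and 0.943 in wild type and 1.13 and 1.16 in the mutant-labelled libraries. The mitochondrial chromosome held 33.1%, 31.7%, 31.0% and 27.8% of counts, in the order wild type 1, wild type 2, mutant 1, mutant 2. The 10 most abundant genes held 36.1%, 35.3%, 32.8% and 29.9%. Across genes, the deviation of a library from the mean of all libraries correlated with transcript length by Spearman's rho of −0.34 in wild type replicate 1 against 0.27, 0.20 and −0.003 in the other libraries; genes are not independent replicates. The common biological coefficient of variation was 0.186. For genes with no count in a group, folds are lower bounds against 3 counts over that group, and with 1 to 3 counts the ratio of counts per effective library is given with its exact interval. A floor of 3 counts corresponds to 0.135 to 0.257 CPM of the library total. Intervals on shares are exact Clopper-Pearson 95% intervals; they and the floors cover counting error only.

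Before the data were examined, 29 gene lists and 17 lists of markers of other cell types or of sex were fixed, with the tests, the alternatives and the rule for named genes. Lists with at least 5 measured members were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 44 lists, with camera at an estimated correlation and fry beside it. Counts of called members are given over all genes and adjusted over the list alone. The rule names Carm1; the 8 largest changes in each direction among called genes with at least 1 CPM in the higher group and groups that do not overlap, skipping gene models without a standard symbol; the 5 most abundant called genes in each direction; up to 4 called members of each gene list by adjusted p, or the 2 most abundant where none was called; up to 2 called members of each marker list; and 4 isoform pairs. Other genes are said to have been chosen after their values were seen.

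The alternatives were DESeq2 size factors, library totals, upper-quartile factors, leaving out mitochondrially encoded genes, no filter on low counts, 1 CPM in at least 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a robust edgeR fit, glmTreat against a log2 fold change of 0.5, an FDR of 0.10, leaving out each library in turn, a block for the replicate number, and for lists a prior count of 0.5. A correction for transcript length and GC content, genes on X and Y left out, and thinning to the smallest library were added after the data were seen. Without a library, a group holds 1 sample that is assumed to vary like the other group. The number of calls then depends on which pair sets the spread, and the wild-type pair differed more than the mutant-labelled pair, as given above. Processed pseudogenes were matched to protein-coding transcripts with BLAST+ 2.17.0 at 90% identity or more over at least 50% of the copy.

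The steps were tested on simulated data for the comparison of mutant-labelled with wild-type libraries: counts of the 15283 genes were drawn from the real means, dispersions and library sizes with 100 genes changed 2-fold and 100 changed 4-fold, all of at least 1 CPM. The edgeR step recovered 54.0% of the 2-fold and 96.0% of the 4-fold changes and called 7 unchanged genes among 159 calls. In the same data camera found a list of 40 genes shifted by −0.7 on the log2 scale, and called 0 of 20 unshifted lists. Genes were drawn independently of each other there, so this does not test camera on lists whose genes vary together.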

Results

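The series profiled RNA from whole mouse hearts at postnatal day 14 by short-read sequencing. There were 2 wild-type libraries and 2 libraries labelled Carm1 mutant. Carm1 encodes a protein arginine methyltransferase that methylates histone H3 and transcriptional coactivators, and the series title places the study in the maturation of heart muscle after birth. The deposited table held counts for 54752 gene identifiers, of which 26469 had at least 1 count. Library totals were 21719161 and 20778420 counts for wild type replicates 1 and 2, and 22217442 and 11677604 counts for mutant replicates 1 and 2. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

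The targeted gene was examined in every library before any other. Carm1 (ENSMUSG00000032185, GRCm38 chromosome 9, 21546894 to 21592623, plus strand) had 803 and 1025 counts in the wild-type libraries and 897 and 432 in the mutant-labelled libraries. After TMM normalisation this was 45.9 and 52.4 CPM against 35.8 and 31.8 CPM. The log2 fold change was −0.54 (SE 0.19), and the edgeR quasi-likelihood FDR was 0.114, so the gene was not called. Its 95% interval ran from −0.97 to −0.10, which corresponds to 50.9% to 93.0% of the wild-type level. Scaling by library totals alone gave a log2 fold change of −0.16. A count summed over the whole gene does not show whether part of the transcript is lost, so these counts neither identify nor contradict a Carm1 allele, and the groups are called wild type and mutant-labelled throughout. The call was made without wild type replicate 1 (log2 fold change −0.64) and without wild type replicate 2 (−0.48). In those fits the mutant-labelled pair alone set the spread.

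Sex-linked transcripts divided the libraries exactly as the labels did. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty together had 1769 and 2236 counts in the wild-type libraries and 7 and 0 in the mutant-labelled libraries. A count of 0 allows up to 0.257 CPM (3 counts of the library total). Xist, the RNA of the inactive X chromosome, had 12 and 15 counts against 8116 and 3921. Both wild-type hearts thus had the transcripts of males and both mutant-labelled hearts those of females, and every difference between the groups below is also a difference between the sexes.

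**Figure D1:**
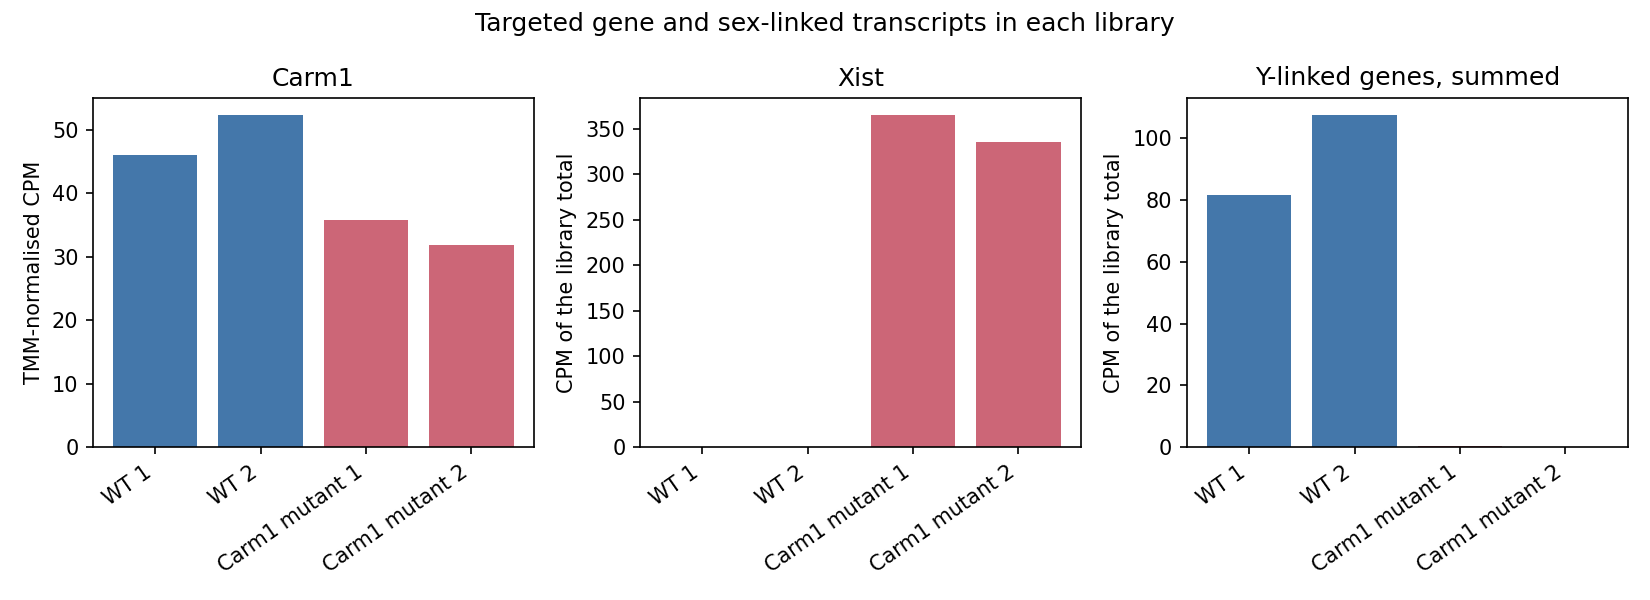
Carm1 (TMM-normalised CPM), Xist and summed Y-linked counts (both CPM of the library total) in each of the 4 libraries, with wild type in blue and mutant-labelled in red; each bar is 1 library. Carm1 lies between 31.8 and 52.4 CPM, while Xist and the Y-linked genes separate the groups completely.

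Transcription differed widely between the groups. Of 15283 genes tested, 1126 passed an edgeR FDR of 0.05, with 426 higher and 700 lower in the mutant-labelled hearts. Of the called genes 865 differed by at least 2-fold, and 1013 were protein coding (373 higher, 640 lower). On the sex chromosomes lay 33, 29 on X and 4 on Y. Of tested X genes 5.8% were called, against 7.4% of autosomal genes. In all 1126 the groups did not overlap, which held for 59.0% of all tested genes against 33.3% by chance in a design of 2 against 2. Scaling by library totals alone shifted the median log2 fold change of all genes by 0.39, which turned the split into 1189 higher and 206 lower, and all 1126 called genes kept their sign. Leaving out a library gave from 377 calls (without mutant replicate 2) through 417 (without mutant replicate 1) and 2294 (without wild type replicate 1) to 5679 (without wild type replicate 2).

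Leaving out gene models without a standard symbol and genes below 1 CPM, the 8 called genes with the largest fitted increases were Xist, Ceacam16, Zfp990, Zfp264, Hist1h2aj, mt-Tg, Slc7a11 and Lilra6. Of these, Ceacam16, Zfp990, Zfp264, Hist1h2aj and mt-Tg had no count in either wild-type library. Against a floor of 3 counts over the wild-type group they were at least 40.4-fold, 34.2-fold, 29.8-fold, 24.4-fold and 21.3-fold higher, at 3.27 ± 0.46, 2.77 ± 0.37, 2.41 ± 0.65, 1.98 ± 0.43 and 1.72 ± 0.07 CPM (SD, n = 2). Slc7a11, the cystine transporter subunit, had 2 counts in the wild-type group and 95 in the other, a ratio of 45.5 per effective library (exact 95% counting interval 12.3 to 382; edgeR FDR 0.0139). Lilra6 had 1 and 37 counts, a ratio of 35.5 (5.98 to 1439; edgeR FDR 0.0323). Among the 8 largest decreases were the Y-linked genes Uty, Ddx3y, Kdm5d and Eif2s3y. Uty was at least 158-fold lower against a floor of 3 counts over the mutant-labelled group. The autosomal genes were Pdzd3, Lgr6, Akr1e1 and Rpl29; Pdzd3 had 51 counts in wild type and 2 in the other group, a ratio of 26.6 (6.99 to 226). Lgr6, a receptor for R-spondins, fell from 58.1 ± 3.8 to 3.93 ± 0.76 CPM (log2 fold change −3.86, SE 0.23, edgeR FDR 4.5e-04, n = 2 each). Akr1e1, an aldo-keto reductase, fell from 22.8 ± 8.3 to 1.58 ± 0.25 CPM (−3.82, SE 0.34, edgeR FDR 0.00294). Rpl29, Zfp990, Zfp264, Hist1h2aj and mt-Tg belong to families with similar copies or have copies elsewhere in the genome, so their values are uncertain, because the way reads were shared between copies is not given in the sources used here.

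Most listed genes of mitochondrial fuel use fell. Of 42 measured genes of fatty acid uptake and oxidation, 27 fell, 0 rose and 15 did not pass the edgeR test (35 lower adjusted over the list alone), with a median log2 fold change of −1.10. Acadvl, the very long-chain acyl-CoA dehydrogenase, fell from 389 ± 68 to 108 ± 3 CPM (log2 fold change −1.85, SE 0.22, edgeR FDR 0.00847). Hsdl2 fell by 1.56 (SE 0.20, edgeR FDR 0.00984), Etfdh, which passes electrons from acyl-CoA dehydrogenases to ubiquinone, by 1.56 (SE 0.22, edgeR FDR 0.0130), and Pdk4, a kinase that restrains pyruvate dehydrogenase, by 1.90 (SE 0.29, edgeR FDR 0.0149) on the log2 scale. Of the 24 genes of the tricarboxylic acid cycle list, 18 fell and 6 did not pass (24 lower adjusted over the list alone, median −1.08). Ogdh, of the 2-oxoglutarate dehydrogenase complex, fell from 2286 ± 9.7 to 1139 ± 23 CPM. Ogdhl (log2 fold change −2.06) and Got1 (−1.50) were also called. The camera FDR was 3.9e-18 for the fatty acid list and 1.8e-13 for the cycle list. Neither passed with an estimated correlation (camera adjusted p = 0.601 for each), a setting in which no list passed, the sex-linked list included. The number of lower calls depended on the libraries: without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn it was 36, 37, 5 and 1 for the fatty acid list and 23, 24, 1 and 1 for the cycle list. The medians moved less: with the libraries left out in that order they were −0.99, −1.28, −1.11 and −1.08 for the fatty acid list. For the cycle list they were −0.87, −1.28, −1.07 and −1.10. With library totals alone the medians were −0.70 and −0.68.

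Some genes of the respiratory chain and its regulators were lower. Of 84 nuclear-encoded oxidative phosphorylation genes, 10 fell and 74 did not pass (14 lower adjusted over the list alone), with a median of −0.71 (camera FDR 9.4e-13, adjusted p = 0.621 with an estimated correlation). Without wild type replicate 1, the library with the strongest trend of expression with transcript length, that median was −0.26 (camera FDR 4.9e-06). Sdha, the flavoprotein of complex II, fell by 1.20 (SE 0.22, edgeR FDR 0.0247), and Atp5a1 and Slc25a4, the heart ADP/ATP carrier, were among the most abundant called genes and fell, from 3725 ± 752 to 1718 ± 142 and from 5211 ± 1524 to 2290 ± 153 CPM. Ndufs5 and Ndufa12 had log2 fold changes of −2.31 and −2.11, but both are uncertain, since near-identical processed copies of them are annotated; a copy of Ndufs5 99.4% identical to it (BC002163, chosen after its values were seen) rose from 2.02 to 98.3 CPM. Among 15 mitochondrially encoded genes 1 fell, mt-Nd4l (log2 fold change −1.75, edgeR FDR 0.0375), and 14 did not pass; the median was −0.55 (camera FDR 7.1e-04, adjusted p = 0.601 with an estimated correlation) and −0.31 without wild type replicate 1. The median of −0.55 lay at percentile 6.77 of random lists matched on abundance, inside their central 95% (−0.66 to −0.48). For genes this abundant those lists were largely drawn from the few genes of the highest ranks, members of the list among them. The comparison therefore cannot tell this list from a trend with abundance. Of 23 PPAR, ERR and PGC-1 regulators, 7 fell and 16 did not pass (9 lower adjusted over the list alone; median −0.41, camera FDR 1.8e-04, adjusted p = 0.601 with an estimated correlation). Perm1, a muscle regulator that acts with PGC-1 and ERR, fell from 273 ± 8 to 84.0 ± 4.8 CPM (log2 fold change −1.70, edgeR FDR 0.00815), Esrrb by 1.61 and Rxrg by 1.23. Without mutant replicate 1 the median of that list was −0.62. Lower calls in the oxidative phosphorylation list numbered 24, 81, 2 and 2 without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn, those in the mitochondrially encoded list 3, 13, 1 and 0, and those in the regulator list 10, 9, 4 and 2. With library totals alone the medians of these lists were −0.29, −0.14 and −0.04.

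Some carbohydrate genes were lower as well. Of 35 genes of glycolysis and lactate handling, 12 fell and 23 did not pass (15 lower adjusted over the list alone; median −0.69, camera FDR 1.5e-05, adjusted p = 0.601 with an estimated correlation), and the median was −0.41 without wild type replicate 1. Pdha1, a subunit of pyruvate dehydrogenase encoded on X, fell by 1.80 (SE 0.22, edgeR FDR 0.00853), Pdhb by 1.26, Slc16a1, a lactate carrier, by 1.24, and Hk2 by 1.12. Of 23 genes of glycogen metabolism, 10 fell and 13 did not pass (15 lower and 1 higher adjusted over the list alone; median −0.73, camera FDR 4.1e-06, adjusted p = 0.601 with an estimated correlation). Phkg1, the catalytic subunit of phosphorylase kinase, fell from 15.3 ± 2.1 to 2.82 ± 0.13 CPM (log2 fold change −2.43, SE 0.24, edgeR FDR 0.00529), and Gys1, glycogen synthase of muscle, from 150 ± 5 to 60.5 ± 0.2 CPM. There were 15, 23, 1 and 1 lower calls in the glycolysis list and 16, 16, 1 and 2 in the glycogen list without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn. Their medians were −0.27 and −0.34 with library totals alone.

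**Figure D2:**
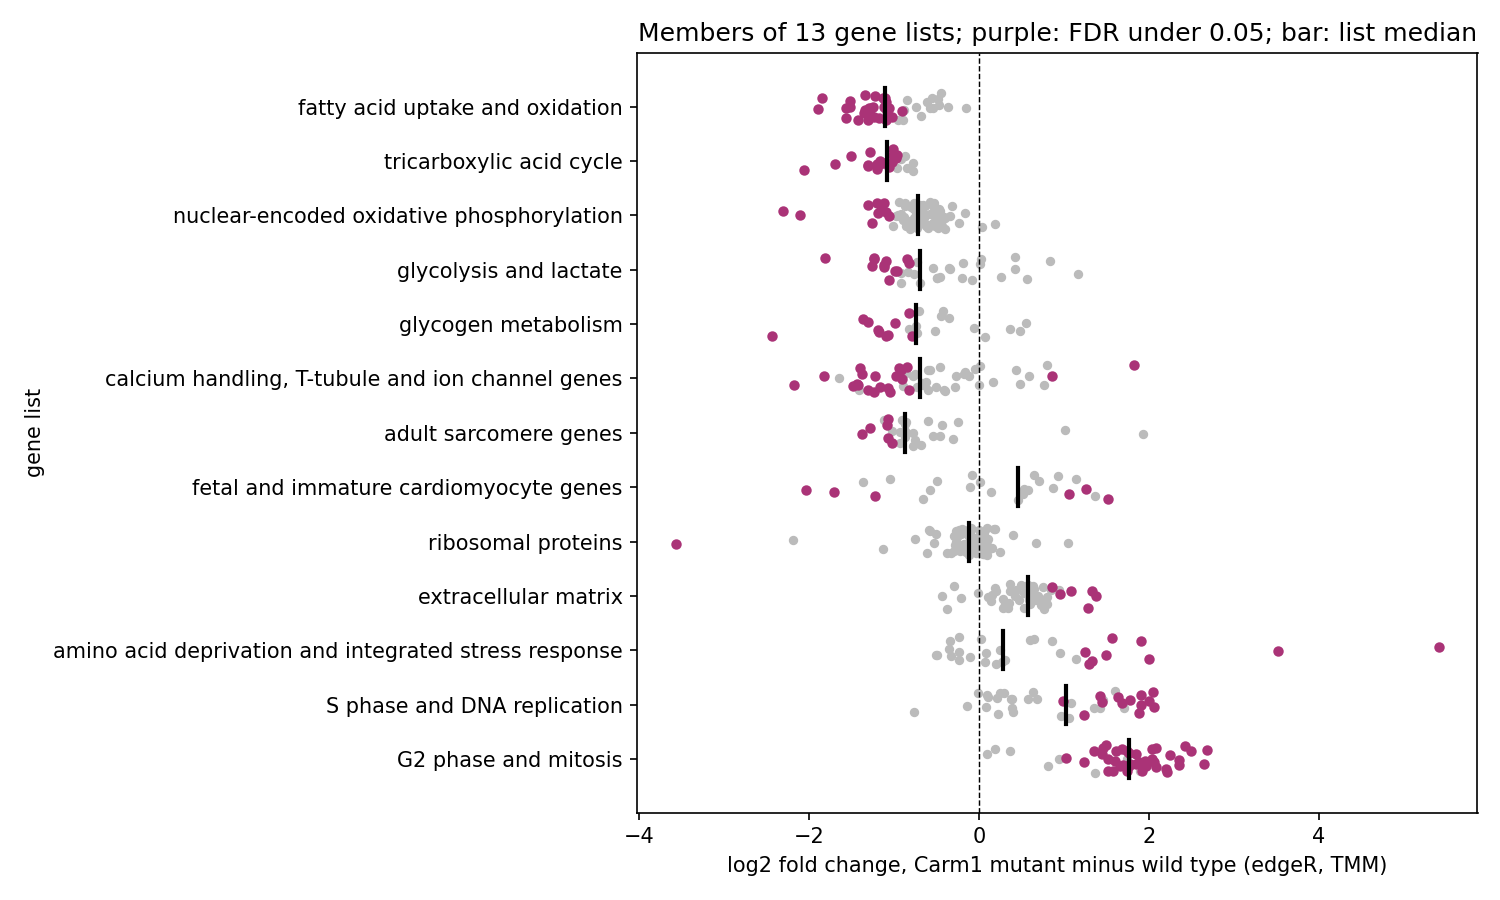
log2 fold change (mutant-labelled minus wild type, edgeR with TMM scaling) of every measured member of 13 gene lists. Each point is a gene, purple points passed an edgeR FDR of 0.05, and black bars are list medians, from −1.10 for fatty acid genes to 1.77 for mitosis genes; the median of the ribosomal list changes sign when library totals alone are used.

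Calcium handling and contractile genes were lower in part. Of 52 calcium handling, T-tubule and ion channel genes, 19 fell, 2 rose and 31 did not pass (30 lower and 3 higher adjusted over the list alone; median −0.70, camera FDR 1.9e-08, adjusted p = 0.601 with an estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 6366 ± 263 to 2283 ± 23 CPM (log2 fold change −1.48, SE 0.25, edgeR FDR 0.0203). Camk2b fell by 2.17, Hrc, a calcium-binding protein of the reticulum, by 1.82, and Kcnj5, a potassium channel, by 1.44 on the log2 scale. Bin1, which shapes T-tubules, rose by 0.87 on the log2 scale and was chosen after its values were seen. Of 29 adult sarcomere genes 6 fell and 23 did not pass (21 lower and 2 higher adjusted over the list alone; median −0.87, camera FDR 2.4e-08, adjusted p = 0.601 with an estimated correlation). Mylk3 (log2 fold change −1.38), Myom1 (−1.28), Pdlim5 (−1.08) and Lmod2 (−1.07) were the called genes with the smallest adjusted p. Without wild type replicate 1 its median was −0.57. The calcium handling list had 29, 33, 5 and 3 lower and 3, 6, 1 and 1 higher calls and the sarcomere list 21, 26, 0 and 0 lower and 1, 1, 0 and 0 higher without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn. With library totals alone their medians were −0.32 and −0.44. The 6 lower calls of the sarcomere list do not by themselves set it apart from other abundant genes, whose lower calls are given above.

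The fetal and immature cardiomyocyte list moved both ways, with 3 genes higher, 3 lower and 19 not passing (8 higher and 6 lower adjusted over the list alone; median 0.46, mean 0.10, camera FDR 0.549). Nes rose by a log2 fold change of 1.52 (edgeR FDR 0.0203), as did Map1b (1.26) and Nppa (1.07), both chosen after their values were seen, while Myl7, Myl4 and Hcn4, genes of atrial and pacemaker cells, fell by 2.04, 1.70 and 1.22. The marker list of atrial cardiomyocytes had 4 genes lower, 1 higher and 10 not passing (8 lower and 1 higher adjusted over the list alone; median −0.64, camera FDR 0.00631, adjusted p = 0.601 with an estimated correlation); its camera FDR was 0.131 without wild type replicate 2, and its median was −1.13 without mutant replicate 1 and −0.24 with library totals alone. In paired isoforms, Myh7 made up 1.05 ± 0.49% of Myh6 plus Myh7 counts in wild type and 3.15 ± 0.47% in the mutant-labelled libraries (SD, n = 2 each). Tnni1 made up 0.264 ± 0.025% of Tnni1 plus Tnni3 against 1.06 ± 0.14%, and Acta1 1.11 ± 0.12% of Acta1 plus Actc1 against 4.07 ± 1.56%. Myl7 of Myl2 plus Myl7 went the other way, 2.29 ± 0.30% against 0.719 ± 0.452%. The genes Myh7, Tnni1 and Acta1 were not called by themselves. No group overlapped the other in any of these shares, but an exact two-sided permutation test of 2 against 2 cannot give a p below 0.333. The median of the fetal list was 0.20 without wild type replicate 2 and 0.22 without mutant replicate 2. It had 9, 8, 3 and 2 higher and 5, 8, 4 and 1 lower calls without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn, and the atrial list 6, 8, 6 and 2 lower calls and 1, 1, 0 and 0 higher. The fetal median was 0.87 with library totals alone.

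**Figure D3:**
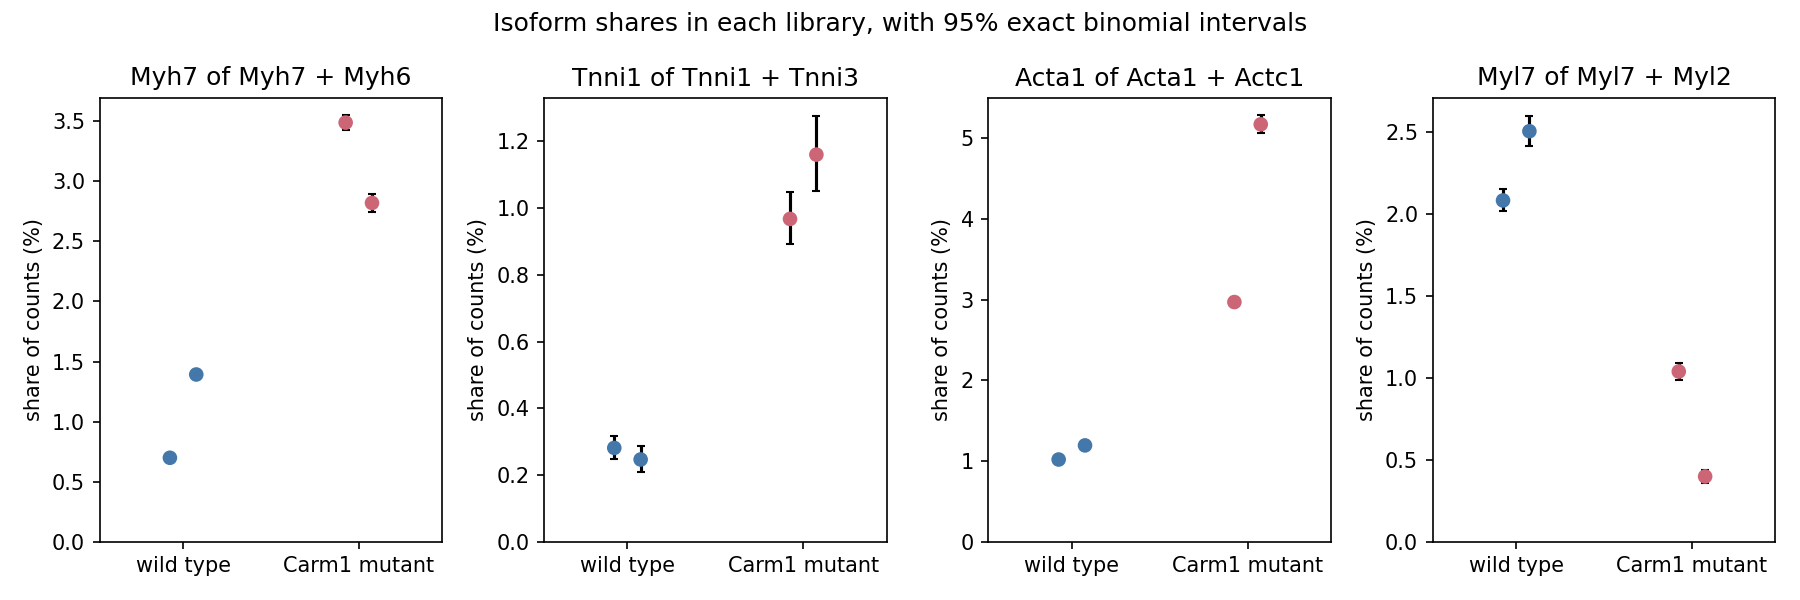
Share of counts (%) of the fetal or atrial isoform in 4 isoform pairs, by group; each point is 1 library (blue wild type, red mutant-labelled) and bars are exact Clopper-Pearson 95% intervals, which cover counting error only. Myh7, Tnni1 and Acta1 shares are higher, and Myl7 shares lower, in both mutant-labelled libraries.

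Mitosis genes rose most, and some S phase genes rose. Of 48 genes of G2 phase and mitosis, 39 rose, 0 fell and 9 did not pass (45 higher adjusted over the list alone), with a median of 1.77 (camera FDR 4.0e-26, adjusted p = 0.601 with an estimated correlation). Ccna2 (cyclin A2) rose from 3.8 ± 0.61 to 18.2 ± 2.6 CPM (log2 fold change 2.25, SE 0.24, edgeR FDR 0.00624). Birc5 rose by 2.21 (SE 0.27, edgeR FDR 0.00847), Tpx2, a spindle assembly factor, by 2.06 (SE 0.24, edgeR FDR 0.00815), and Ube2c by 1.92 (SE 0.22, edgeR FDR 0.00769). Of 38 genes of S phase and DNA replication, 13 rose and 25 did not pass (20 higher and 1 lower adjusted over the list alone; median 1.03, camera FDR 5.4e-09, adjusted p = 0.601 with an estimated correlation). Chaf1b (log2 fold change 2.06), Rad51ap1 (2.01), E2f1 (1.69) and Rrm2 (1.43) had the smallest adjusted p. Of 22 cell cycle exit genes 3 fell, Ccng1 (−1.02), E2f6 (−0.87) and Tob1 (−0.82), and 19 did not pass (3 lower and 1 higher adjusted over the list alone; median 0.21, camera FDR 0.863). Higher calls numbered 42, 44, 32 and 30 in the mitosis list and 18, 18, 11 and 6 in the S phase list without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn. The 3 lower calls among cell cycle exit genes were 0 without mutant replicate 1 and 0 without mutant replicate 2, and the median of that list was 0.15, 0.15, 0.065 and 0.27 in the order of the libraries above and 0.60 with library totals alone. Higher calls in it were 2, 2, 0 and 0 in that order.

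Genes of the response to amino acid deprivation were partly induced. Of 30 members 9 rose, 0 fell and 21 did not pass (13 higher adjusted over the list alone; median 0.29, camera FDR 0.00494, adjusted p = 0.601 with an estimated correlation). Gdf15, a secreted stress cytokine, rose from 3.83 ± 0.65 to 43.9 ± 6.3 CPM (log2 fold change 3.52, SE 0.24, edgeR FDR 8.6e-04). Mthfd2, of mitochondrial one-carbon metabolism, rose by 1.90 and Slc7a5, an amino acid carrier, by 1.33. Without wild type replicate 2 the list had a median of 0.14 and a camera FDR of 0.0839, and without mutant replicate 1 and wild type replicate 1 medians of 0.48 and 0.44. The list of p53 target genes had 5 higher, 2 lower and 16 not passing (7 higher and 5 lower adjusted over the list alone; median 0.40, camera FDR 0.0784). It passed without mutant replicate 2 (median 0.43, camera FDR 0.0335). Psrc1, a spindle protein (log2 fold change 2.62), and Gtse1 (1.75), also in the mitosis list, were among its called genes. The list of hypertrophy and injury genes had 5 higher, 2 lower and 29 not passing (6 higher and 2 lower adjusted over the list alone; median 0.29, camera FDR 0.0840), among them Thbs1 (1.40) and Thbs4 (1.49) higher and Fhl2 (−1.68) lower; without mutant replicate 1 it passed (median 0.42, camera FDR 0.00873), and without wild type replicate 1 its median was 0.17 (camera FDR 0.0790). Immediate early genes had 4 higher and 20 not passing (5 higher and 1 lower adjusted over the list alone; median 0.38, camera FDR 0.0456, adjusted p = 0.601 with an estimated correlation), led by Egr2 (2.39); the camera FDR was 0.0583, 0.173 and 0.0644 without wild type replicate 1, wild type replicate 2 and mutant replicate 1, and the median without wild type replicate 2 was 0.24. In the amino acid deprivation list 12, 12, 6 and 6 genes were called higher without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn. The p53 list had 6, 8, 4 and 4 higher and 3, 5, 0 and 0 lower calls in that order, the hypertrophy list 11, 12, 3 and 0 higher and 2, 6, 0 and 0 lower, and the immediate early list 7, 8, 3 and 1 higher and 1, 2, 0 and 0 lower. With library totals alone the medians of the amino acid deprivation, p53, hypertrophy and immediate early lists were 0.69, 0.81, 0.67 and 0.77.

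Some matrix genes were higher, and of the endothelial and fibroblast markers 1 each. Of 49 extracellular matrix genes 6 rose and 43 did not pass (15 higher adjusted over the list alone; median 0.58, camera FDR 6.4e-07, adjusted p = 0.601 with an estimated correlation), and the median was 0.38 without wild type replicate 1. Postn (periostin) rose from 223 ± 9.5 to 581 ± 98 CPM (log2 fold change 1.38, SE 0.23, edgeR FDR 0.0189), Col15a1 by 1.08 and Tnc (tenascin C) by 1.34. Mfap4, Neat1 and Plxnd1 were the other abundant genes that rose, by 1.22, 1.68 and 1.04; Neat1 had 84.6 and 207 CPM in the wild-type libraries, and its log2 fold change was 1.16 without wild type replicate 1. Malat1, another abundant nuclear RNA (chosen after its values were seen), was also low in wild type replicate 1, at 226 CPM against 495, 486 and 526 in the other libraries, and was not called (edgeR FDR 0.400). Endothelial markers had 1 of 20 higher, Cldn5 (log2 fold change 1.12; 6 higher adjusted over the list alone; median 0.44, camera FDR 6.3e-04, adjusted p = 0.601 with an estimated correlation). Fibroblast markers had 1 of 17 higher, Pi16 (0.93; 9 higher adjusted over the list alone; median 0.57, camera FDR 0.0113, adjusted p = 0.601 with an estimated correlation), and the camera FDR was 0.0850, 0.0594 and 0.0786 without wild type replicate 2, mutant replicate 1 and mutant replicate 2. Markers of pericytes and smooth muscle (15 genes, median −0.04, camera FDR 0.863) and of macrophages (17 genes, median 0.12, camera FDR 0.689) had no called member. With library totals alone the medians were 0.96 for the matrix list and 0.81, 0.97, 0.34 and 0.53 for endothelial, fibroblast, pericyte and macrophage markers. Without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 the pericyte median was −0.23, 0.15, 0.039 and −0.045 and the macrophage median 0.11, −0.031, 0.24 and 0.023. Higher calls numbered 14, 37, 3 and 0 in the matrix list, 6, 14, 0 and 0 among endothelial markers and 9, 6, 0 and 0 among fibroblast markers without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn.

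The remaining lists held few called genes. Cardiac transcription factors had 6 of 36 lower, including Irx3 (log2 fold change −1.83), Tbx5 (−1.33) and Srf (−0.94; 7 lower and 2 higher adjusted over the list alone). Their median was −0.27 (camera FDR 0.0101, adjusted p = 0.601 with an estimated correlation), but 0.11 with library totals alone, and the camera FDR was 0.173 without wild type replicate 2. Imprinted growth genes had 1 of 23 higher, Mest (1.73, edgeR FDR 0.00647; 1 higher adjusted over the list alone), with a median of 0.35 (camera FDR 0.0342, adjusted p = 0.621 with an estimated correlation). That median was 0.09 without wild type replicate 1 (camera FDR 0.462), 0.17 without mutant replicate 1 (camera FDR 0.166) and 0.68 without wild type replicate 2. Lysosome and autophagy genes had 2 of 40 lower, Mitf (−1.28) and Bnip3 (−1.04; 2 adjusted over the list alone), with a median of −0.28 that was 0.11 with library totals alone (camera FDR 0.0366, adjusted p = 0.601 with an estimated correlation). Leaving out wild type replicate 1, mutant replicate 1 or mutant replicate 2 gave that list a camera FDR of 0.146, 0.0598 and 0.0885 and medians of −0.13, −0.27 and −0.17. Protein arginine methyltransferases and coactivators had 1 of 24 higher, Padi4 (2.03), and no other member passed (1 adjusted over the list alone; median 0.16, camera FDR 0.303). Lower calls without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 in turn numbered 10, 12, 3 and 2 among cardiac transcription factors (higher calls 2, 8, 0 and 0) and 4, 13, 1 and 0 among lysosome genes, and higher calls 2, 7, 1 and 2 among imprinted genes and 1, 5, 1 and 1 among methyltransferases (lower calls 1, 4, 0 and 0). The median of the methyltransferase list was 0.078, 0.18, 0.12 and 0.22 in the same order, and with library totals alone it was 0.55 and that of the imprinted list 0.74.

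Ribosomal protein genes had 1 of 80 called, Rpl29 (log2 fold change −3.57), with a median of −0.11 (1 lower adjusted over the list alone, camera FDR 0.303). This median depended on the libraries and on scaling: it was 0.35 without wild type replicate 1 (camera FDR 1.7e-05), −0.51 without wild type replicate 2 (camera FDR 3.4e-09), −0.22 without mutant replicate 2 (camera FDR 0.0244) and 0.31 with library totals alone. No member was called among 28 genes of cholesterol and fatty acid synthesis (0 adjusted over the list alone; median 0.11, camera FDR 0.747) or 25 of the unfolded protein response (0 adjusted over the list alone; median −0.07, but 0.32 with library totals alone, camera FDR 0.177); without mutant replicate 2 the latter list had a median of −0.30 (camera FDR 0.0262). Splicing regulators had 2 of 28 lower, Rbm38 (−1.04) and Rbfox1 (−1.11; 2 adjusted over the list alone; median 0.07, camera FDR 0.898). The IGF, thyroid hormone and glucocorticoid list had 3 lower and 1 higher of 28, with Thrb (1.10) higher and Igfbp3 (−1.22), Angptl4 (−1.10) and Pdk4 lower (3 higher and 3 lower adjusted over the list alone; median −0.28, but 0.12 with library totals alone, camera FDR 0.303). Without mutant replicate 1 its median was −0.45 (camera FDR 0.0114), without wild type replicate 2 −0.13 (camera FDR 0.702) and without mutant replicate 2 it was 0.0060 (camera FDR 0.935). Interferon-stimulated genes had Xaf1 (1.02) higher and Rsad2 (−1.43) lower of 40 (1 lower adjusted over the list alone; median −0.13, but 0.27 with library totals alone, camera FDR 0.177). Circadian clock genes had Nr1d1 (−1.05) lower of 20 (1 higher and 1 lower adjusted over the list alone; median −0.10, but 0.29 with library totals alone, camera FDR 0.693). Without wild type replicate 2 there were 51 lower calls among ribosomal protein genes, 8 lower among unfolded protein response genes, and 8 higher and 7 lower in the IGF list. The same fit gave 5 higher calls among splicing regulators, 5 higher and 4 lower among interferon-stimulated genes and 4 higher and 2 lower among clock genes, and without wild type replicate 1 there were 9 higher calls among ribosomal protein genes. Without mutant replicate 2 the calls in the splicing, interferon and circadian lists were all lost. The medians of the cholesterol and splicing lists were 0.51 and 0.46 with library totals alone. Medians without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 were 0.15, −0.063, 0.11 and 0.12 for cholesterol synthesis and −0.10, −0.25, 0.071 and −0.30 for the unfolded protein response. In that order they were −0.095, 0.10, 0.047 and 0.089 for splicing, −0.19, −0.18, −0.057 and −0.25 for interferon and −0.16, 0.026, −0.18 and −0.041 for clock genes.

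Among the other marker lists, lymphocyte markers had no called member of 8 (median 0.47, camera FDR 0.0366, adjusted p = 0.601 with an estimated correlation; camera FDR 0.137 without wild type replicate 1, median 0.79 without wild type replicate 2). Valve and cartilage markers had 2 of 13 higher, Sox9 (log2 fold change 1.70) and Ptn (1.31), with a median of 0.45 (4 higher adjusted over the list alone, camera FDR 0.0456, adjusted p = 0.601 with an estimated correlation). That list had a camera FDR of 0.290 without wild type replicate 1 and 0.145 without mutant replicate 2, and medians of 1.11, 0.68 and 0.22 without wild type replicate 2, mutant replicate 1 and mutant replicate 2. Epicardial markers had Wt1 (0.99) higher of 13 (1 adjusted over the list alone) while their median was −0.64 (camera FDR 0.247); without mutant replicate 1 it was −1.51 (camera FDR 1.6e-05) and without mutant replicate 2 it was −0.16 (camera FDR 0.786). The conduction system list had Hcn4 lower of 12 (1 lower and 1 higher adjusted over the list alone; median 0.36, camera FDR 0.579) and skeletal muscle Myl1 (−1.01) lower of 8 (1 adjusted over the list alone; median 0.04, with camera in the lower direction at FDR 0.857). No member was called among markers of endocardium (6 genes, 1 higher adjusted over the list alone, median 0.13, camera FDR 0.168), Schwann cells and neurons (12 genes, median 0.37, camera FDR 0.164), erythroid cells (8 genes, 1 lower adjusted over the list alone, median −0.29, but 0.11 with library totals alone, camera FDR 0.247) or adipocytes (5 genes, median −0.23, but 0.20 with library totals alone, camera FDR 0.365). Endocardium passed without wild type replicate 2 (median 0.88, camera FDR 0.00902) and had a median of −0.26 without wild type replicate 1 (camera FDR 0.782). Erythroid markers passed without mutant replicate 2 (−0.76, camera FDR 0.00301), and adipocyte markers without wild type replicate 2 (−0.87, camera FDR 0.0145) and without mutant replicate 2 (−0.86, camera FDR 0.0329), with a median of −0.064 without wild type replicate 1 (camera FDR 0.723). Lung epithelium and neutrophil markers had 3 measured genes each, none called, and were not tested as lists. The sex-linked list had 4 lower and 1 higher of 5 (camera FDR 4.8e-04, adjusted p = 0.601 with an estimated correlation). Without mutant replicate 2 the valve, epicardial, conduction and skeletal muscle lists had 0 calls; without mutant replicate 1 the epicardial list had 6 lower calls, and without wild type replicate 2 the conduction list had 6 higher and the endocardial list 5 higher. The median without wild type replicate 1, wild type replicate 2, mutant replicate 1 and mutant replicate 2 was 0.096, 0.76, 0.28 and 0.42 for the conduction list and 0.30, −0.19, −0.060 and −0.35 for the skeletal muscle list, and it was −0.54 without wild type replicate 1 for erythroid markers. Under library totals alone the medians were 0.87 for lymphocyte, 0.85 for valve, −0.26 for epicardial, 0.72 for conduction, 0.46 for skeletal muscle, 0.49 for endocardial and 0.77 for Schwann cell and neuron markers.

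Of the 44 lists tested, 23 passed a camera FDR of 0.05, 10 higher and 13 lower. With an estimated correlation 0 passed, not even the sex-linked list with its median of −8.52 (camera adjusted p = 0.601). That setting, with 2 residual degrees of freedom, therefore tells no list from another. The sex-linked list is a weak check on it, with 4 genes lower and 1 higher of 5. The preset correlation of 0.01 takes genes of a list to vary almost independently, so its camera FDRs allow little for genes that vary together. The ribosomal median, for example, was 0.35 without wild type replicate 1 and −0.51 without wild type replicate 2. Fry asks only whether the genes of a list move on balance in 1 direction. It passed 1, the calcium handling list (fry FDR 0.00501). The log2 fold change followed abundance: the 68 most abundant genes had a median of −0.66 and the 1821 genes at or below 1 CPM a median of 0.38. Among the lists that passed camera, the medians of the mitochondrially encoded, cardiac transcription factor, lysosome, lymphocyte and valve lists lay inside the central 95% of random lists matched on abundance. For the mitochondrially encoded list that decides nothing, for the reason given above. Among the genes given by the naming rule, in 48 the call was lost without mutant replicate 1, in 61 without mutant replicate 2, in 62 when tested against a log2 fold change of 0.5 and in 24 with library totals alone, and none of them changed sign under any of these settings. For called genes the sign was all but fixed in fits without a library, because their groups did not overlap. The medians of lists not called by camera changed sign without wild type replicate 1 (ribosomal proteins, splicing, endocardium), wild type replicate 2 (cholesterol synthesis, circadian clock, pericytes, macrophages, skeletal muscle), mutant replicate 1 (unfolded protein response, pericytes, skeletal muscle) or mutant replicate 2 (IGF list, skeletal muscle).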

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

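The tests with length and GC correction, with X and Y genes left out and with thinning were chosen after the data were seen. Called genes kept their sign under every alternative in which they had a value. Without a library this was all but fixed in advance, because in every called gene the groups did not overlap. The other fits used the same libraries. The 1126 calls became 2630 without a filter on low counts (1169 higher, 1461 lower), 226 against a log2 fold change of 0.5 (111 and 115), 2488 at an FDR of 0.10 (1077 and 1411) and 2756 with length and GC correction (1093 and 1663); the thresholds of 0.5 and 0.10 are stricter and looser by construction, and for the filter and the correction the cause was not tested. Library totals alone gave 1189 higher and 206 lower, from the shift of 0.39, and the DESeq2 Wald test 1141 lower of 1669, for which the cause was not tested. The other scalings and fits and the other filter gave 1060 to 1161 calls. Leaving out 1 library gave 377 to 5679 calls, with 221 to 2553 higher and 156 to 3126 lower; a group then rests on 1 sample.

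Carm1 was not called, but it was with length and GC correction (log2 fold change −0.62, edgeR FDR 0.0238), for which the cause was not tested. It was also called without wild type replicate 1 or replicate 2. Leaving out 1 library gave log2 fold changes of −0.64 to −0.47, so the effect moved little. The pair of libraries that set the spread changed between these fits. The 23 lists past the threshold became 0 with camera at an estimated correlation, which did not pass even the sex-linked list, and 1 with fry. The number was 19 with library totals alone and 19 with length and GC correction. It was 20 with upper-quartile factors and 20 with 1 CPM in at least 2 libraries. The remaining settings that kept every library gave 21 to 23. The list of ribosomal proteins reversed, to a median of 0.35, without wild type replicate 1; leaving out 1 library gave −0.51 to 0.35, and the cause was not tested. The replicate numbers are shared between groups, but nothing in the labels pairs them, and differences between same-numbered libraries correlated by −0.247 over 2 pairs; a replicate block gave 1222 calls (580 higher, 642 lower), 941 of them shared with the fit without it, and 22 lists, and 9 genes of the naming rule were not called in it. Mutant replicate 2 has the fewest counts (11677604), and thinning all libraries to it gave 1219 calls, 1034 of them shared.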

Other observations

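Groups of genes in the paragraph that follows were chosen after the named genes were seen, and all tests in this part were chosen after the results they bear on, except the test of pseudogenes and their parent genes, before which single pairs such as Ndufs5 and its copy had been seen.

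Some genes of other mitochondrial pathways were lower too. Of 21 genes that break down branched-chain amino acids 9 fell and 0 rose, with a median log2 fold change of −0.85 (camera FDR 1.7e-09 over these 4 groups and the 44 lists, adjusted p = 0.404 with an estimated correlation, as for each of the 4 groups). Ivd, isovaleryl-CoA dehydrogenase, fell from 180 ± 3 to 52.5 ± 0.6 CPM (log2 fold change −1.78, edgeR FDR 0.00641), Mccc1 by 1.58 and Bckdha, a subunit of the branched-chain 2-oxoacid dehydrogenase, by 1.58. Of 77 mitochondrial ribosomal protein genes 7 fell and 0 rose (median −0.59, camera FDR 1.7e-10), led by Mrpl3 (−1.50). Of 22 genes of mitochondrial protein import 4 fell (median −0.57, camera FDR 1.8e-04), and of 21 genes of haem synthesis and iron uptake 5 fell (median −0.49, camera FDR 0.00280). Alas1, which starts haem synthesis, fell from 515 ± 51 to 123 ± 10 CPM and Tfrc, the transferrin receptor, from 285 ± 22 to 83.7 ± 5.4 CPM. All 4 groups passed camera in the lower direction, and none with an estimated correlation. Since they were picked after called members had been seen, this does not test whether genes of other mitochondrial groups fell with the fatty acid genes.

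Metabolic and calcium-handling lists were lower and mitotic lists higher. On transcript length or GC bias between libraries, all 8 lists tested (fatty acid, TCA, oxidative phosphorylation, glycogen, calcium handling, sarcomere, S phase, mitosis) still passed in the same direction after a correction for both. The imprinted, lysosome, immediate early and valve lists no longer passed with it (camera FDR 0.0573, 0.0525, 0.0573 and 0.0618). Passing at the preset correlation was a low bar for the 8 lists, so it weighs little against such a bias. The oxidative phosphorylation median was −0.63 with the correction but −0.26 without wild type replicate 1. The correction thus did not remove the dependence on that library. The fatty acid medians were −1.05 and −0.99 in these settings, and the mitosis medians 1.78 and 1.58. Against a trend with abundance or the library scaling, list medians were compared with 10000 random lists matched on abundance. The fatty acid and mitosis lists lay at percentiles 0 and 100, and the other 6 lists at 0.06 or lower or at 100. Part of the falls goes with abundance, since the random medians centred on −0.41 (fatty acid), −0.52 (TCA) and −0.49 (oxidative phosphorylation). They centred on −0.12 for glycogen and −0.18 for calcium handling. The matching decides nothing for the mitochondrially encoded list, at 6.77, because its random lists came largely from few genes. That limit also touches the sarcomere list, whose random medians had the same centre of −0.53. A lower share of cardiomyocytes, with the other cells in fixed proportion, would raise markers of those cells alike. Endothelial, fibroblast, pericyte and macrophage markers moved apart (permutation p = 1e-05 over 69 genes, the smallest that the permutations can give). Genes are not independent replicates, and with library totals alone all 4 medians lay above 0 (0.81, 0.97, 0.34 and 0.53). The test does not bear on a share lost to endothelial cells and fibroblasts alone, whose markers had medians of 0.44 and 0.57. What stays open is the Carm1 genotype and the sex of the hearts, which cannot be told apart because 0 groups hold libraries of both sexes. A lower share of cardiomyocytes of that kind stays open too, as does a bias of wild type replicate 1 in the oxidative phosphorylation list. A difference in developmental stage may also be involved and was not tested.

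Calls that crowd on chromosome 2, and copies that change against their parent genes, formed a second pattern. The window from 115 to 120 Mb of chromosome 2 held 14 calls among 46 tested genes (hypergeometric adjusted p = 0.00167). That from 70 to 75 Mb of chromosome 9 held 9 among 29 (hypergeometric adjusted p = 0.0406). Carm1 is on this chromosome but far outside that window, starting at position 21546894. The fullest window of shuffled calls often held as many as 14 (permutation p = 0.424, median 13). That count can come from windows with many tested genes, so it does not bear on crowding relative to the number of genes tested. Ndufs5 fell from 143 ± 47 to 28.9 ± 2.1 CPM while its processed copy BC002163 rose from 2.02 ± 0.70 to 98.3 ± 11.1 CPM, and their sum was 145 and 127 CPM. Over the 51 called processed pseudogenes with a tested parent, 51.0% of parents had the opposite sign (26 parents, one-sided exact binomial p = 0.5). Among 747 uncalled copies the share was 30.8%. The test takes equal odds as its null, not the share among uncalled copies, and counts parents with several copies, such as Rpl29, more than once. It also pools both directions: most copies that rose had a parent that fell, and most copies that fell had a parent that fell too. Reads moved between copies and a difference in genetic background between the groups may each contribute, and these tests decide neither.

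Carm1 counts that differed little between the groups were the third pattern. A wild-type and a mutant library exchanged would hide a loss of Carm1 only if each group held 1 library with much less of it. With either possible exchange undone, the Carm1 log2 fold change was −0.18 (95% interval −0.96 to 0.60) or −0.044 (−0.87 to 0.78), so no loss by 1 or more on the log2 scale was hidden this way. A mutation that leaves most of the counted transcript remains possible: the log2 fold change of −0.54 cannot be told apart from it, because counts per exon were not analysed here.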
